A study of Homo sapiens with 32 samples.

How the data were processed

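The deposited table holds raw read counts per gene symbol for 32 libraries, and no read was realigned here. The authors made these counts, per the submitters' processing notes, by demultiplexing with bcl2fastq 2.0, aligning to the human genome hg38 with TopHat2 2.1.0 and Bowtie2 2.2.6.0, checking quality with FastQC and counting with HTSeq. The versions of HTSeq, FastQC and the edgeR the authors used, the annotation, the strand setting and any filter are not given in the sources used here. Per the labels' protocols, cells were kept in phenol red-free medium with charcoal-treated serum, transfected with siRNA and treated with ligand for 18 hours. Libraries were prepared with a TruSeq kit and read on a NextSeq 500.

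All 32 columns were matched to sample titles, 2 of them under the suffix bis that was dropped for the match, and 0 were left unmatched. Groups are those of the labels throughout, 4 siRNA labels by 4 ligand labels with 2 libraries in each of 16 groups, and no library was moved to another group or left out. No paired analysis is given because replicate numbers follow accession order only and the labels name no pairing. That order coincides with odd and even title numbers in every group, and a fit with the main within-group component as covariate was added after this was seen. Symbols were matched to GENCODE v29 on GRCh38 for positions, exonic length and GC content.

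Genes with too few counts were removed by the filterByExpr rule of edgeR 4.0.16 (minimum count 10 for the 16 groups), which left 15471. Libraries were scaled by TMM, and edgeR's quasi-likelihood test with robust dispersions was fitted to 16 group means, leaving 16 residual degrees of freedom. The siRNA effects were averages over the 4 ligand labels, 8 against 8 libraries, the ligand effects were taken without siRNA, 2 against 2, and interactions were differences of differences. The 17 comparisons, 8 of them interactions, were fixed before the data were examined, each adjusted over genes by the Benjamini-Hochberg method at 0.05. Counts of genes for a ligand label averaged over the siRNA labels were planned as a second reading, while the genes and lists of those averages and the ligand effects under each siRNA label were added later. Standard errors are the fold change over the square root of F. Levels are log2 CPM, counts scaled to the library total, with a prior count of 2. A fold against a group at 0 counts is a lower bound with a floor of 3 counts per library.

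LCOR and NRIP1 were reported in every group. The other named genes were the 8 largest rises and 8 largest falls of the main comparisons, or 4 each way for the others, past the threshold with a mean of at least 1 log2 CPM, a symbol and the same direction in every replicate or ligand condition. Up to 4 members of a described list were added. GREB1, PGR and DHRS3 were chosen after their values were seen.

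Of 25 fixed lists, 23 had at least 5 members tested: estrogen-induced, estrogen-repressed and retinoic acid target genes, nuclear receptors, coregulators, S phase, G2/M phase, interferon response, integrated stress response, endoplasmic reticulum chaperones, p53 targets, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, Wnt targets, epithelial-mesenchymal transition, luminal, basal and immune markers, ribosomal proteins, immediate early genes and NF-kB targets. Fibroblast markers had 2 of 10 members tested, and of 13 mitochondrially encoded genes the table holds 0, so neither list was analysed here. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated, and with fry, each adjusted over lists within a comparison. DESeq2 1.42.0 was the second method. Work was done in R 4.3.3 and Python 3.11.15, with matplotlib 3.10.9 for the figures.

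The code was run on simulated counts with 200 of 15471 genes changed. For the E2 comparison it found 19% of 2-fold and 78% of 4-fold changes with 6 false calls, for the LCoR comparison 70% and 100% with 11, and for the interaction of E2 with LCoR 2% and 40% with 4.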

Results

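Gene expression was measured by RNA sequencing of 32 libraries from MELN cells, a derivative of the MCF-7 breast cancer line that carries an estrogen-responsive luciferase reporter. The labels set 4 siRNA conditions (none, LCoR, RIP140 or both) against 4 ligand conditions: ethanol vehicle, 100 nM estradiol (E2), 10 µM all-trans retinoic acid (RA), or both ligands for 18 hours. Each of the 16 groups held 2 libraries, and nothing in the labels says whether the duplicates are separate cultures. The p values therefore measure only the spread between these libraries, which can be technical or, as given below, a difference between conditions. The libraries without siRNA carry no mention of a control siRNA. The comparisons ask how the estrogen receptor, its coregulators LCoR and RIP140 and the retinoic acid receptors act together on transcription. Libraries held 32648164 to 43231900 counts over 26927 gene symbols, of which 15471 had enough counts to be tested. Totals this large limit low genes by counting error only, while the spread between labelled duplicates was wide. What edgeR names the biological coefficient of variation was 0.355. The main component of this spread held 65% of the variance within groups, with odd and even title numbers at opposite signs in every group.

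Genes that respond to the ligands divided the libraries against their labels. CYP26A1, the retinoic acid hydroxylase that retinoic acid induces (chromosome 10, 93073475 to 93077890, GRCh38), had 11774 to 41341 counts in all 16 libraries labelled E2 or E2+RA. In the 16 libraries labelled vehicle or RA it had 1 to 12 counts. DHRS3, a retinaldehyde reductase and retinoic acid target (chromosome 1, 12567910 to 12617731), had 5121 to 11159 counts against 43 to 160 over the same division. TFF1, a secreted peptide induced by estradiol (chromosome 21, 42362282 to 42366594), divided every labelled pair of duplicates. It stood at 9.54 to 12.23 log2 CPM (counts scaled to library size) in the 16 libraries with an even number in their title and at 6.46 to 8.88 in the 16 with an odd number, each pair holding 1 of each. The pair labelled vehicle without siRNA had 18298 and 179731 TFF1 counts. GREB1 (chromosome 2, 11482341 to 11642788) lay at 7.80 to 9.62 and 5.32 to 6.45 log2 CPM over that division, and PGR, the progesterone receptor gene (chromosome 11, 101029624 to 101130524), at 5.36 to 7.99 and 1.88 to 3.34. TFF1 also followed the CYP26A1 division among odd and among even numbers, lower under the E2 or E2+RA labels without overlap. Among odd numbers it lay at 6.46 to 7.39 log2 CPM against 8.60 to 8.88 under vehicle or RA. Among even numbers these were 9.54 to 10.45 and 11.68 to 12.23. Every direction given here is a difference between labels, and these marker genes went against the ligand labels, so what each comparison contrasts is uncertain.

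LCOR was not lower in the libraries labelled LCoR siRNA, nor NRIP1 in those labelled RIP140 siRNA alone. LCOR, the gene of LCoR (chromosome 10, 96832282 to 96995959), ranged from 2.98 to 4.76 log2 CPM in the 8 libraries labelled without siRNA, from 2.84 to 4.90 under the LCoR label, from 3.30 to 5.76 under RIP140 and from 3.29 to 5.50 under both. Its difference under the LCoR label was 0.07 ± 0.27 log2 (SE, 8 against 8 libraries; edgeR quasi-likelihood test, adjusted p = 1.0). NRIP1, the gene of RIP140 (chromosome 21, 14961235 to 15065936), ranged from 5.04 to 8.40 without siRNA, from 3.64 to 7.30 under LCoR, from 4.96 to 8.85 under RIP140 and from 2.94 to 7.54 under both. Its difference was 0.63 ± 0.50 log2 for the RIP140 label and -1.02 ± 0.50 for both siRNAs (edgeR adjusted p = 0.454 and 0.209). The libraries labelled both differed from those labelled RIP140 by -1.65 ± 0.51 log2 in NRIP1 (edgeR adjusted p = 0.662). An edgeR fit with a within-group component as covariate was added. That component was taken from the spread of these same libraries, so the standard errors and p values of this fit can be too small. In it NRIP1 differed by -1.24 ± 0.21 log2 under both siRNAs (edgeR adjusted p = 0.000184). Its difference was -1.73 ± 0.21 for both against RIP140 and -1.02 ± 0.21 under the LCoR label (edgeR adjusted p = 0.000136 and 0.0318). Under RIP140 alone NRIP1 was not lower, at 0.49 ± 0.21 (edgeR adjusted p = 0.067). The fall thus followed the LCoR and both labels, title numbers 25 to 32, and not the RIP140 label. LCOR was higher in that fit under RIP140 by 0.83 ± 0.16 log2 (edgeR adjusted p = 0.000338) and under both by 0.69 ± 0.16 (edgeR adjusted p = 0.00189). LCOR lay at 2.84 to 4.61 log2 CPM in the libraries labelled RA or E2+RA, title numbers 21 to 24 and 29 to 32, and at 3.06 to 5.76 in the others. The RA label against vehicle, averaged over the siRNA labels, had a difference of -0.94 ± 0.27 log2 in LCOR (edgeR unadjusted p = 0.00264, adjusted p = 0.66). Under every siRNA label the mean LCOR level was lower with RA than with vehicle, and lower with E2+RA than with E2. The E2+RA and E2 means were 3.56 and 3.91 log2 CPM without siRNA and 4.13 and 5.47 under both. LCOR was thus lower in other libraries than those labelled LCoR siRNA. NRIP1 was higher under the E2 label, by 2.18 ± 0.52 log2 averaged over the siRNA labels (edgeR adjusted p = 0.00561).

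**Figure D1:**
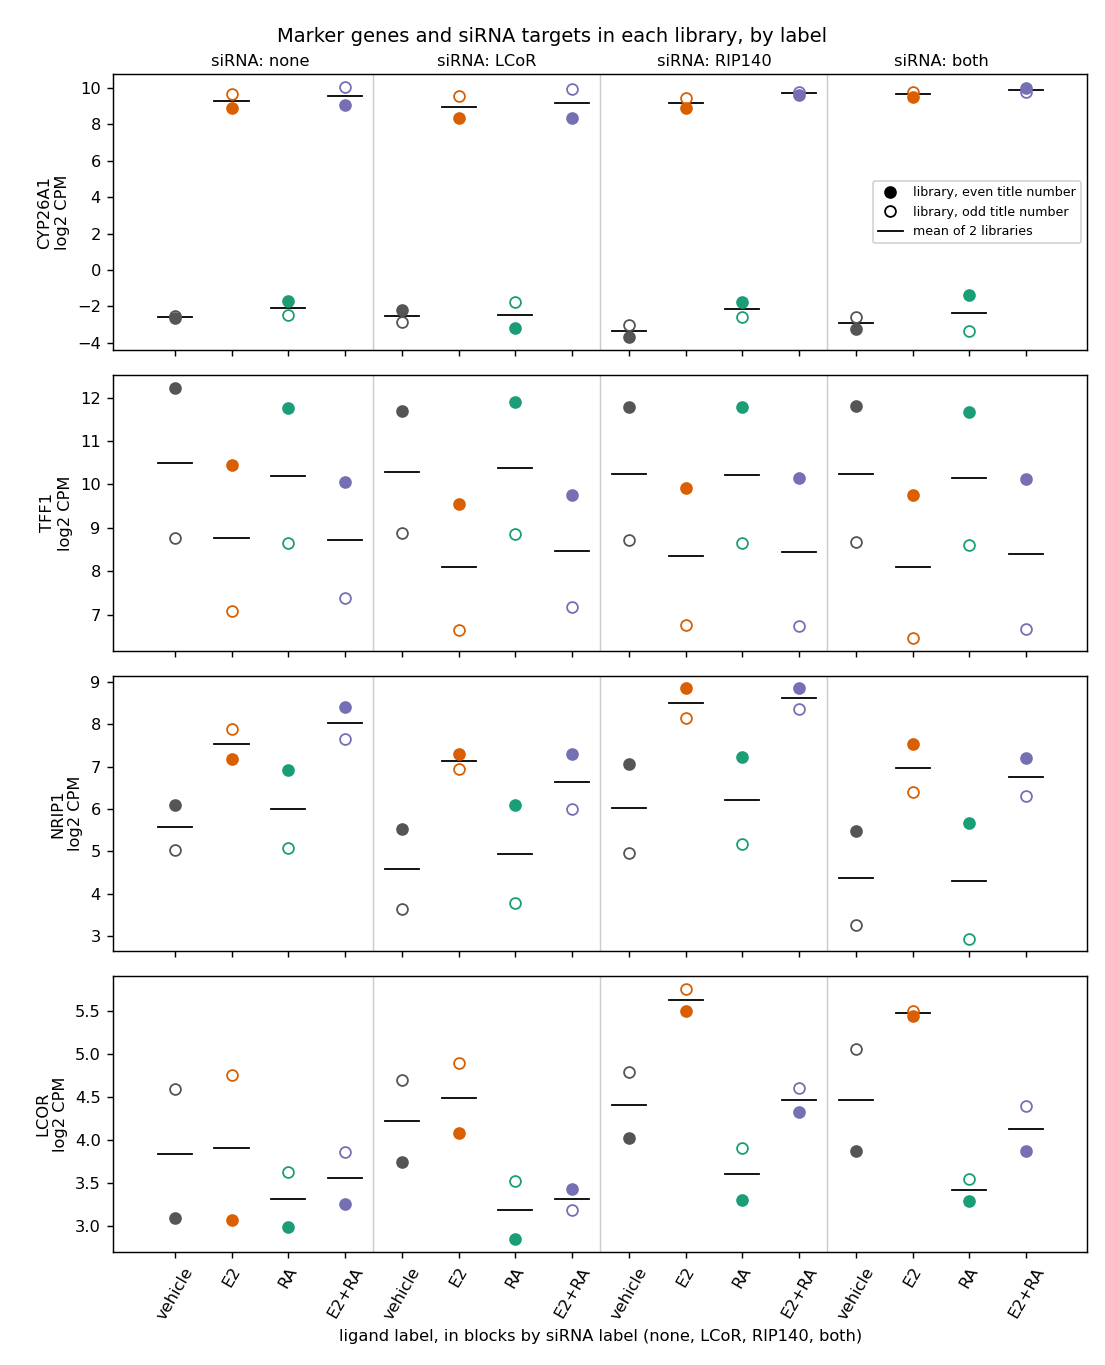
Level of CYP26A1, TFF1, NRIP1 and LCOR in each library (log2 CPM, vertical axis) by labelled group (horizontal axis); circles are libraries, filled for an even and open for an odd title number, and bars are means of 2 libraries. CYP26A1 lay at 8.36 to 10.05 in the libraries labelled E2 or E2+RA and at -3.70 to -1.38 in the others, while TFF1 split each labelled pair.

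The first principal component held 34.1% of the variance and the second 28.1%. Together they placed the libraries in 4 clusters, set by the division that CYP26A1 shows and by odd or even title number. In 0 of 32 libraries was the labelled duplicate the most similar library, and in 32 of 32 the title number of the most similar library differed by a multiple of 4. The title prefix S6 marks the libraries without siRNA or with LCoR, and S7 those with RIP140 or both, so prefix and these siRNA labels cannot be told apart.

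**Figure D2:**
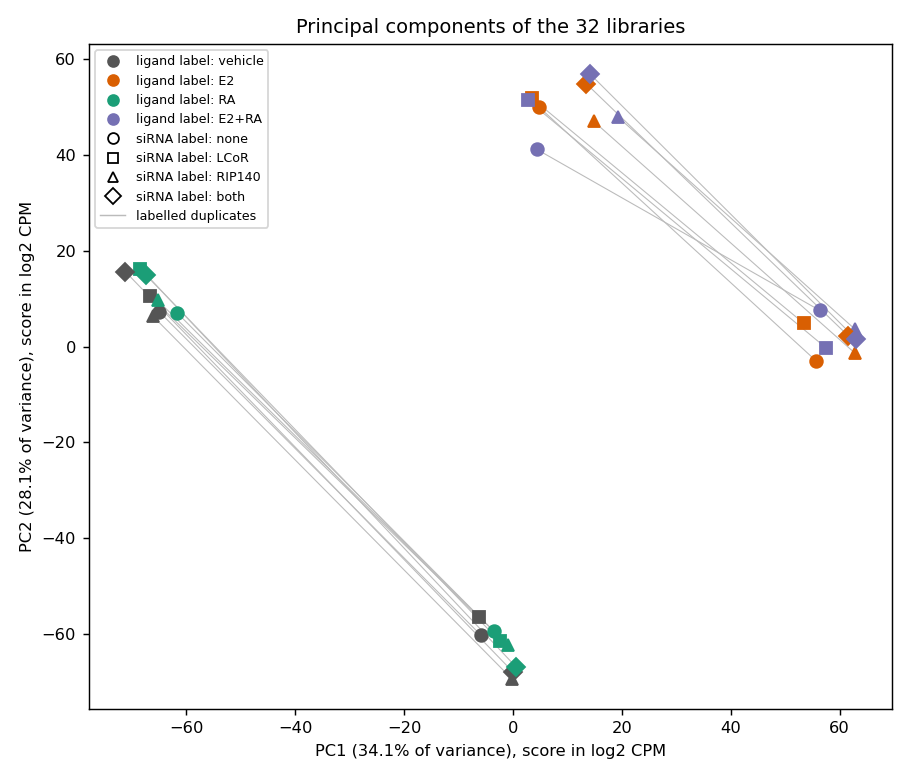
Scores of the 32 libraries on the first (34.1% of variance, horizontal) and second (28.1%, vertical) principal components of log2 CPM, coloured by ligand label and shaped by siRNA label, with a line joining labelled duplicates. All 16 lines cross between clusters, and no cluster mixes E2 or E2+RA labels with vehicle or RA labels.

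The first comparison asks which genes respond to estradiol alone. In the libraries labelled E2 without siRNA, retinoic acid targets were far above the libraries labelled vehicle, and KRT1, KRT16 and TNFRSF11B were among the genes below them. CYP26A1 rose by 12.44 ± 0.90 log2 (SE, 2 against 2 libraries; edgeR quasi-likelihood test, adjusted p = 1.25e-07), from 5 and 4 counts to 36983 and 14941. TMPRSS4, a membrane serine protease, rose by 8.34 ± 0.79 log2 and KIAA0125 by 8.16 ± 1.52 (edgeR adjusted p = 4.62e-06 and 0.00618). Several genes were nearly silent under the vehicle label and passed the test. ADCY5, an adenylyl cyclase, went from 0 and 2 counts to 3521 and 1212, PTGS1, a cyclooxygenase, from 3 and 3 to 3952 and 2442, CDH5, the endothelial cadherin, from 5 and 2 to 5720 and 1354, and STRA6, the retinol transporter, from 4 and 0 to 1106 and 328. TNFSF15, a cytokine of the tumour necrosis factor family, was at least 37.3-fold higher, with a floor of 3 counts per library for its 2 libraries at 0. KRT1 fell from 267 and 179 counts to 1 and 2. KRT16 fell by 4.82 ± 0.46 log2 (edgeR adjusted p = 4.78e-06), though keratins with close copies are uncertain. TNFRSF11B, the gene of osteoprotegerin, fell by 5.79 ± 1.07 log2 (edgeR adjusted p = 0.00582). IGFL1, MAOA (monoamine oxidase), ABCA12 (a lipid transporter), CASP14 (a caspase of keratinocytes) and ACTG2 (a smooth muscle actin) were lower, at -4.89 ± 1.08, -3.99 ± 0.93, -3.55 ± 0.50, -3.34 ± 0.50 and -3.16 ± 0.45 log2. In all, 145 genes were higher and 124 lower (269 in total by edgeR's quasi-likelihood test, 526 by DESeq2). Without the first or the second vehicle library the total was 88 or 109, and without the second E2 library 159. A fit of only the groups compared gave 2, and the within-group component as covariate 1550.

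Among the fixed gene lists, the retinoic acid targets stood apart under the E2 label. Of 26 tested, 5 were higher and 0 lower, and 13 were higher when adjusted over the list alone. DHRS3 rose by 6.55 ± 0.68 log2, ELF3, an epithelial transcription factor, by 3.30 ± 0.46, and TNFAIP2 by 2.96 ± 0.38 (SE, 2 against 2 libraries; edgeR adjusted p = 1.68e-05, 0.00049 and 0.000186). Their median change was 1.55 log2 (camera adjusted p = 2.5e-13, adjusted p = 0.00532 with an estimated correlation). Of 31 estrogen-induced genes, 0 were higher and 1 was lower: TFF3, a secreted peptide next to TFF1 (chromosome 21, 42311667 to 42315651), fell by 1.72 ± 0.36 log2 (edgeR adjusted p = 0.0154). Their median was -0.39 (camera adjusted p = 0.457), and none of the 14 estrogen-repressed genes passed (camera adjusted p = 0.253). Members passed in 6 other lists. NR2F2, an orphan nuclear receptor and 1 of 24 nuclear receptors, rose by 1.77 ± 0.40 log2, DDIT3, 1 of 16 genes of the integrated stress response, by 0.86 ± 0.17, GDF15, 1 of 18 p53 targets, by 2.82 ± 0.68, and CD14, 1 of 5 immune markers, by 3.12 ± 0.56. The mean level of CD14 over all libraries was low, at -1.24 log2 CPM. KRT17, 1 of 8 basal markers, fell by 2.16 ± 0.37 log2. Of 15 NF-kB targets 1 was higher, TNFAIP2 as above, and 1 lower, RELB, which fell by 1.21 ± 0.27 log2. In the lists of coregulators, S phase, G2/M phase, interferon response, endoplasmic reticulum chaperones, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, Wnt targets, epithelial-mesenchymal transition, luminal markers, ribosomal proteins and immediate early genes, 0 members passed by edgeR, and no list but the retinoic acid targets was called by camera. These comparisons rest on the labels that the marker genes went against.

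The RA label asks about retinoic acid alone. Without siRNA, it set apart 0 genes by edgeR's quasi-likelihood test and 0 by DESeq2, with 196 at an unadjusted p under 0.05 in edgeR. CYP26A1 had 5 and 9 counts under the RA label and 5 and 4 under vehicle, and 0 of 26 retinoic acid targets passed, with a median of 0.003 log2. Camera called oxidative phosphorylation and glycolysis lower, each at adjusted p = 0.000619, ribosomal proteins lower at adjusted p = 0.0269 and NF-kB targets higher at adjusted p = 0.00454. None of these calls held, at adjusted p = 0.724, 0.463, 0.911 and 0.262 with an estimated correlation.

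Libraries labelled E2+RA held more retinoic acid target mRNA than those labelled vehicle, with CYP26A1 higher by 12.75 ± 0.91 log2 (SE, 2 against 2 libraries; edgeR adjusted p = 9.48e-08). Counts of ADCY5 were 2178 and 1009, of PTGS1 2763 and 2118, and of TNFSF15 130 and 140 under the E2+RA label, against 0 and 2, 3 and 3, and 0 and 0 under vehicle. KRT1 was at least 65.3-fold lower, with 0 counts in both E2+RA libraries. TNFRSF11B and KRT16 were lower, at -5.53 ± 1.06 and -5.49 ± 0.48 log2 (edgeR adjusted p = 0.00599 and 1.9e-06), and CASP14 went from 72 and 46 counts to 3 and 2. In all, 363 genes were higher and 256 lower (619 by edgeR, 1174 by DESeq2). Of 26 retinoic acid targets, 7 were higher and 0 lower, 13 higher adjusted over the list alone, with a median of 2.61 log2 (camera adjusted p = 7.63e-10, adjusted p = 0.0214 with an estimated correlation). NR2F2 rose by 1.72 ± 0.40 log2, GDF15 by 3.13 ± 0.69, FAS, a death receptor, by 1.22 ± 0.26 and CCL20, a chemokine, by 1.73 ± 0.36. TFF3 fell by 2.04 ± 0.36 log2, CYR61, a matricellular protein gene, by 1.44 ± 0.30, and VDR, the vitamin D receptor gene, by 1.19 ± 0.32. The second library labelled E2+RA listed 5371 genes at 0, against 8906 to 10069 in the other 7 libraries without siRNA. Leaving it out gave 223 genes, and leaving out the first or the second vehicle library gave 153 each time. With only the groups compared in the fit it was 15, and with the within-group component 3367.

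Against the RA label, which asks what estradiol adds to retinoic acid, the E2+RA libraries showed CYP26A1 higher by 12.06 ± 0.88 log2 (SE, 2 against 2 libraries; edgeR adjusted p = 1.36e-07). PTGS1 went from 2 and 0 counts to 2763 and 2118 and CDH5 from 5 and 0 to 3569 and 1349. TNFSF15 was at least 48.7-fold higher and KRT1 at least 44.7-fold lower. TNFRSF11B, KRT16 and IGFL1 were lower, at -5.95 ± 1.07, -5.04 ± 0.47 and -4.16 ± 1.04 log2. In all, 348 genes were higher and 179 lower (527 by edgeR, 934 by DESeq2). Of 26 retinoic acid targets, 8 were higher and 0 lower, 13 higher adjusted over the list alone, with a median of 2.21 log2 (camera adjusted p = 9.16e-11, adjusted p = 0.0145 with an estimated correlation). Among 24 nuclear receptors, 4 were higher, NR2F2 by 1.85 ± 0.40 log2 and NR2F6 by 1.17 ± 0.28 among them. Camera also called ribosomal proteins higher, though 0 of 34 passed singly (adjusted p = 0.000957, adjusted p = 0.946 with an estimated correlation), and NF-kB targets lower (adjusted p = 0.0363, adjusted p = 0.368 with an estimated correlation). Without the first or the second RA library the total was 96 or 92, and without the second E2+RA library 159. In a fit of only the groups compared 0 genes passed by edgeR, and with the within-group component 2735.

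Set against the E2 label, the E2+RA libraries showed no gene past the main test. The retinoic acid targets had a median of 0.006 log2 and 0 of 26 passed. By edgeR's quasi-likelihood test 0 genes passed, with 1082 at an unadjusted p under 0.05, and 111 passed by DESeq2, 104 of them higher. Coregulators were called lower by camera with a median of -0.33 log2 (adjusted p = 0.00967, adjusted p = 0.658 with an estimated correlation), HDAC6, a deacetylase, at -0.70 ± 0.31 and NCOR2, a corepressor, at -0.50 ± 0.28 log2. With the within-group component as covariate 96 genes passed, 88 of them higher. Without the first E2+RA library, which left the one with few genes at 0, 252 genes passed. The interaction of the E2 and RA labels called 0 genes by edgeR and 0 by DESeq2, with 506 at an unadjusted p under 0.05 in edgeR, and 93 without that first library.

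**Figure D3:**
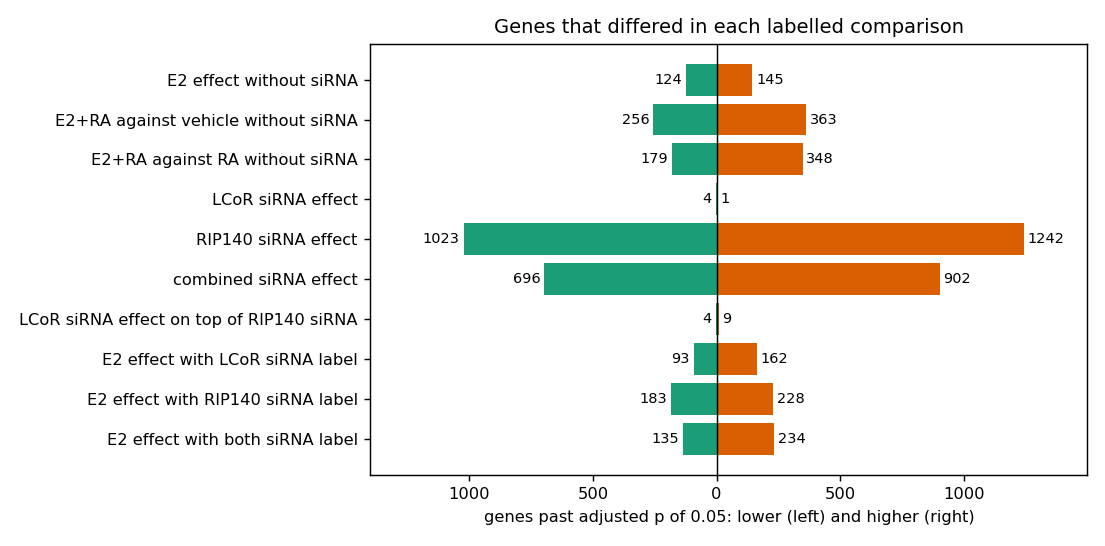
Genes past an adjusted p of 0.05 by edgeR's quasi-likelihood test (horizontal axis: number of genes, higher to the right and lower to the left of 0) for each labelled comparison with at least 1 such gene. The RIP140 label gave 1242 higher and 1023 lower genes, the LCoR label 1 and 4.

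The E2 label set retinoic acid targets apart under each other siRNA label too. CYP26A1 had at least 11774 counts in every library labelled E2 or E2+RA, whichever the siRNA label. The E2 label gave 255 genes with LCoR siRNA, 411 with RIP140 siRNA and 369 with both, by edgeR. Of 26 retinoic acid targets, 6, 7 and 7 were higher and 0 lower (camera adjusted p = 4.52e-13, 4.77e-12 and 1.3e-20, adjusted p = 0.00585, 0.00863 and 0.000527 with an estimated correlation). The RA label gave 0 genes under each of these siRNA labels by edgeR, with 138, 296 and 114 at an unadjusted p under 0.05. By the labels, the interactions ask whether an siRNA changes a response to a ligand. The ligand markers went against these labels, and LCOR and NRIP1 were not lower under the LCoR and RIP140 labels. The RIP140 label also coincides with the title prefix. Counts of 0 here therefore do not answer that question. Those of the E2 label with the LCoR, RIP140 and combined siRNA labels each gave 0 genes by edgeR, with 103, 69 and 114 at an unadjusted p under 0.05, and 0, 1 and 0 by DESeq2. Those of the RA label gave 0 genes each by edgeR, with 74, 60 and 44 at an unadjusted p under 0.05, and 0 by DESeq2. Among the list calls of these interactions, those of E2 with both siRNAs passed camera for NF-kB targets (median 0.55 log2, adjusted p = 0.00955 with an estimated correlation) and cholesterol synthesis (median 0.16, adjusted p = 0.0103 with an estimated correlation), but not fry (adjusted p = 0.162 for each). TNFAIP2, an NF-kB target as well, had a difference of 1.73 ± 0.51 log2 and MSMO1, a sterol oxidase, of 0.77 ± 0.44, neither past the test. Camera called retinoic acid targets higher for that interaction too (median 0.32 log2, adjusted p = 3.83e-05, adjusted p = 0.0748 with an estimated correlation). No other interaction list call passed with an estimated correlation. On simulated counts the interaction of E2 with LCoR found 40% of 4-fold and 2% of 2-fold changes among 15471 genes, so this interaction had little power for changes of that size.

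The LCoR label, read without RIP140 siRNA, went with small differences in a few genes that were not LCOR. NRIP1, lower with this label in the fit with a covariate, differed by -0.86 ± 0.50 log2 in the main fit and did not pass. MAEA, part of an E3 ubiquitin ligase, fell by 0.70 ± 0.07 log2, MLX, a dimer partner of glucose-sensing transcription factors, by 0.55 ± 0.07, ACBD5, a peroxisomal membrane protein, by 0.76 ± 0.10 and LMCD1 by 0.82 ± 0.14 (SE, 8 against 8 libraries; edgeR adjusted p = 0.000184, 0.000866, 0.00248 and 0.028). COQ9, a protein of ubiquinone synthesis, rose by 0.65 ± 0.10 log2 (edgeR adjusted p = 0.0145). These 5 were all the genes called by edgeR, against 26 by DESeq2. No fixed list was called by camera, the retinoic acid targets having a median of -0.07 log2 and the estrogen-induced genes of -0.17. Without the first E2 library 8 genes passed, and 3 without the second RA or the second E2+RA library, all labelled without siRNA. Fitting only the groups compared gave 0, and the within-group component 64.

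The same label read on top of RIP140 siRNA uses other libraries, those labelled both against those labelled RIP140. ACBD5 fell by 0.91 ± 0.10 log2, MAEA by 0.62 ± 0.07 and MLX by 0.43 ± 0.07, and COQ9 rose by 0.72 ± 0.10 (SE, 8 against 8 libraries; edgeR adjusted p = 0.000518, 0.000653, 0.012 and 0.00553). THBD, the gene of thrombomodulin, rose by 0.91 ± 0.14 log2, PXK by 0.65 ± 0.12 and FAM127B by 0.61 ± 0.11, and MATN2, a matrix protein gene, fell by 0.84 ± 0.15. By edgeR 9 genes were higher and 4 lower (13 in total, 51 by DESeq2). Outside the rule for named genes and chosen after their values were seen, GSTP1, AIFM2, AGBL5, MRPL34 and C7orf73 made up the rest, all higher. GSTP1, a glutathione transferase, rose by 1.84 ± 0.34 log2 (edgeR adjusted p = 0.0463). Of the 5 genes called without RIP140 siRNA, 4 were among these 13, and all 14 genes called in either set had the same direction in both. Under each prefix the LCoR label coincides with title numbers 25 to 32, so the label cannot be told apart from title number, and nothing says that libraries of the same number under S6 and S7 are separate samples. NRIP1 was lower at these numbers too in the fit with a covariate, and LCOR was not, so these genes cannot be assigned to LCoR siRNA. Camera called oxidative phosphorylation, ribosomal proteins and immune markers higher (adjusted p = 0.000323, 0.0136 and 0.0136, adjusted p = 0.993, 0.993 and 0.608 with an estimated correlation), while the difference fell with exonic length across genes (Spearman rho = -0.261). With 1 library left out, 4 to 11 genes passed. The count was 4 without the first and 5 without the second vehicle library labelled RIP140, 6 without either E2 library, 4 without the second RA library, and 6 or 7 without an E2+RA library of that label. It was 7 without the first vehicle library labelled both and 8 without either E2 or either E2+RA library of that label. Fitting only the groups compared gave 3, and the within-group component 145.

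**Figure D4:**
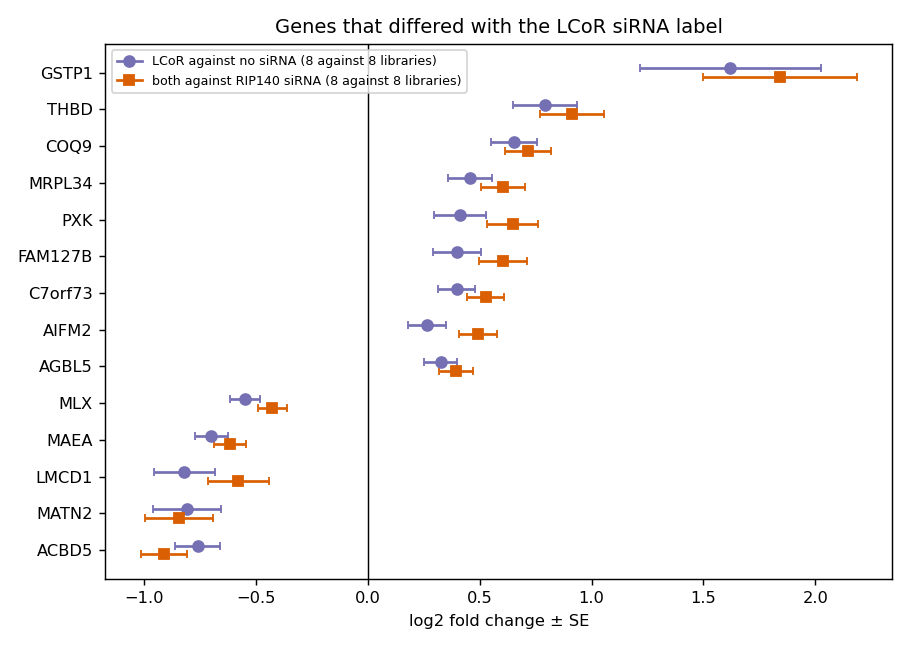
Log2 fold change (horizontal axis, point ± SE) of the 14 genes (vertical axis) called for the LCoR label without RIP140 siRNA (circles, 8 against 8 libraries) or on top of it (squares, 8 against 8 other libraries). All 14 had the same sign in both, from ACBD5 at -0.76 and -0.91 to GSTP1 at 1.62 and 1.84.

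Libraries labelled RIP140 siRNA differed from those without siRNA in many genes, CASP14, KRT1 and KRTDAP being among the largest rises and SOCS3 and FOS among the largest falls. CASP14 rose by 3.07 ± 0.24 log2, KRT1 by 2.98 ± 0.57 and KRTDAP, a keratinocyte differentiation gene, by 2.11 ± 0.17 (SE, 8 against 8 libraries; edgeR adjusted p = 7.88e-07, 0.00317 and 7.88e-07). SGMS2 (a sphingomyelin synthase), ADD3 (an adducin), MARCKS (a kinase C substrate), CXADR (a cell adhesion receptor) and ABCA12 rose by 1.46 ± 0.28, 1.34 ± 0.26, 1.32 ± 0.28, 1.32 ± 0.28 and 1.31 ± 0.23 log2. TNFRSF11B fell by 1.73 ± 0.48 log2, C15orf48 by 1.57 ± 0.21, AKR1B10 (an aldo-keto reductase) by 1.43 ± 0.38, SNHG25 by 1.29 ± 0.32 and VTN, the gene of vitronectin, by 1.27 ± 0.37. SOCS3, an inhibitor of cytokine signalling, fell by 1.26 ± 0.23 log2 and FOS, an immediate early gene, by 1.14 ± 0.24 (edgeR adjusted p = 0.00224 and 0.00469). WFDC21P fell by 2.08 ± 0.57 log2, but as a pseudogene its counts are uncertain. In all, 1242 genes were higher and 1023 lower (2265 by edgeR), of which 44 and 66 changed at least 2-fold. NRIP1 itself was not lower, as given above, and the label cannot be told apart from the title prefix. With only the vehicle libraries contrasted, within the main fit, 1 gene passed. Fitting only the groups compared gave 1492, and the within-group component 5852. Without the second vehicle or the second E2 library labelled without siRNA, 1279 or 1405 genes passed.

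Of the fixed lists, camera called 3 for the RIP140 label, and fry called 3 others. In the G2/M phase list 9 of 26 genes were higher and 0 lower, 11 higher adjusted over the list alone, with CENPF, a kinetochore protein, up 1.13 ± 0.15 log2 and KIF20A, a mitotic kinesin, up 0.77 ± 0.08 (SE, 8 against 8 libraries; camera adjusted p = 1.41e-05, adjusted p = 0.975 with an estimated correlation). Ribosomal protein genes, whose many pseudogenes leave their counts uncertain, were lower in 12 of 34, and in 22 adjusted over the list alone. RPS27 fell by 0.54 ± 0.12 log2 and RPS15 by 0.51 ± 0.11 (camera adjusted p = 9.25e-10, adjusted p = 0.975 with an estimated correlation). In oxidative phosphorylation 8 of 24 were lower, among them COX6C at -0.91 ± 0.25 and NDUFA1 at -0.70 ± 0.11 log2 (camera adjusted p = 0.0046, adjusted p = 0.975 with an estimated correlation). Fry called coregulators and cholesterol synthesis (adjusted p = 0.0408 each) and NF-kB targets (adjusted p = 0.00996), none of them called by camera. Among 24 coregulators MED1, a Mediator subunit, rose by 0.66 ± 0.11 log2 and NCOR1, a corepressor, by 0.63 ± 0.14, with 5 higher and 1 lower. Among 27 interferon response genes 6 were higher and 3 lower, with OAS2 up 0.62 ± 0.13, STAT1 up 0.53 ± 0.12 and IFI27 at -0.43 ± 0.11 log2. Of 15 NF-kB targets 3 were lower, CXCL8 by a change of -1.02 ± 0.22 and RELB of -0.66 ± 0.13 log2. The luminal keratins KRT8, KRT18 and KRT19 changed by -0.49 ± 0.09, -0.27 ± 0.08 and -0.40 ± 0.13 log2. STARD4, a sterol carrier, rose by 0.83 ± 0.14 log2, TFF3 by 1.18 ± 0.18, MDM2, a p53 target, by 0.55 ± 0.11, and the fatty acid oxidation genes HADHA and HADHB by 0.42 ± 0.09 and 0.51 ± 0.11. Across genes, the difference rose with exonic length (Spearman rho = 0.353) and fell with GC content (rho = -0.447), and genes are not independent replicates.

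Both siRNAs together, against none, also went with many differences. KRT1 rose by 2.75 ± 0.56 log2, CASP14 by 2.33 ± 0.24, KRTDAP by 2.14 ± 0.17, ADD3 by 1.38 ± 0.26 and SGMS2 by 1.31 ± 0.28 (SE, 8 against 8 libraries). SLCO2A1, a prostaglandin transporter, rose by 2.57 ± 0.74 log2, CXCL17, a chemokine, by 1.48 ± 0.45 and TFF3 by 1.33 ± 0.18 (edgeR adjusted p = 0.0319, 0.0421 and 0.000239). TNFRSF11B fell by 1.89 ± 0.48 log2, CGA, the glycoprotein hormone alpha chain, by 1.61 ± 0.38, STC1, stanniocalcin, by 1.52 ± 0.28, SOCS3 by 1.48 ± 0.23, C15orf48 by 1.48 ± 0.21, MATN3 by 1.36 ± 0.27 and RGS16 by 1.34 ± 0.26, and the pseudogene WFDC21P by 1.96 ± 0.57. In all, 902 genes were higher and 696 lower (1598 by edgeR), 51 and 92 of them at least 2-fold. In the G2/M phase list 7 of 26 were higher and 0 lower, with CENPF up 1.01 ± 0.15 and AURKA, a mitotic kinase, up 0.54 ± 0.13 log2 (camera adjusted p = 2.34e-05, adjusted p = 0.89 with an estimated correlation). The difference also rose with exonic length (Spearman rho = 0.238) and fell with GC content (rho = -0.427) across genes. Ribosomal proteins were called lower with 2 of 34 passing (camera adjusted p = 1.02e-06, adjusted p = 0.89 with an estimated correlation) and interferon response higher with 4 of 27 (adjusted p = 0.0297, adjusted p = 0.89 with an estimated correlation). Of 15 NF-kB targets 2 were lower, CXCL8 at -0.96 ± 0.22 and RELB at -0.60 ± 0.13 log2 (camera adjusted p = 0.0218, adjusted p = 0.282 with an estimated correlation). Fry called NF-kB targets lower and cholesterol synthesis higher, each at adjusted p = 0.00269. Camera did not call cholesterol synthesis (adjusted p = 0.089, adjusted p = 0.282 with an estimated correlation). LRAT, which esterifies retinol, was the retinoic acid target that passed, up 1.03 ± 0.22 log2 but at -0.029 in the vehicle libraries alone, and AR, the androgen receptor gene, rose by 1.04 ± 0.26. The title prefix cannot be told apart from this label either, nor can title number, 25 to 32 against 17 to 24. LCOR was not lower under it, as given above. With only the vehicle libraries contrasted, within the main fit, 0 genes passed by edgeR, with 625 at an unadjusted p under 0.05. A fit of only the groups compared gave 247, and the within-group component 5288. Of the libraries labelled without siRNA, leaving out the second vehicle gave 787 genes and the first E2 2533. Leaving out the second E2 or the second RA library labelled both gave 1043 or 1059.

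By the labels, the interaction of LCoR and RIP140 asks whether the siRNAs act other than additively. With LCOR and NRIP1 not lower under the LCoR and RIP140 labels, it cannot answer that. It gave 0 genes by edgeR and 0 by DESeq2, with 109 at an unadjusted p under 0.05 in edgeR. LCOR differed by -0.21 ± 0.38 log2 and NRIP1 by -0.79 ± 0.70. Camera called immune markers higher (adjusted p = 0.00334, adjusted p = 0.207 with an estimated correlation), though 0 of 5 passed singly. Of these, MS4A1 and PTPRC, at 7.95 ± 2.25 and 2.96 ± 1.33 log2, had very low mean levels of -2.71 and -2.83 log2 CPM.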

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

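Of the tests below, those on DNA or unspliced RNA, on another cell type and on the title series were written before their results were seen, and the other tests were chosen after. A criterion set earlier, that at least 24 of 32 libraries be most similar to the library of the same title number, failed with 1 of 32. The NRIP1 test was extended to a fit with a covariate after 0.63 ± 0.50 log2 had been seen.

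The retinoid and estrogen markers divided the libraries against their labels. Right ligand labels with duplicates that responded differently are unlikely, because 11 of 26 fixed retinoic acid targets had all 8 libraries labelled E2 alone above all 8 labelled RA alone, and 0 had the RA libraries above those labelled E2 or vehicle, and so is library depth, as the library with more TFF1 had the larger total in 6 of 16 pairs. That each labelled pair holds 2 conditions that differ in estrogen response, as after a shift of titles or count columns against treatments, is likely. Within pairs 31 of 31 fixed estrogen-induced genes were higher in the even-numbered library, with a median of 1.73 log2 against -0.28 to 0.40 in 10000 random lists, and 14 of 14 estrogen-repressed genes lower, with a median of -1.57. Libraries of the same title number under S6 and S7 were less dispersed than labelled pairs (0.0445 against 0.126, and 0.104 to 0.16 in 20 random pairings). They were also more alike (median r = 0.631 against 0.04). Once prefix means were removed, 11 of 32 were most similar to each other. That count cannot decide whether they are the true duplicates, as libraries 4 numbers apart share the CYP26A1 and TFF1 divisions. The siRNA targets argue against the siRNA labels and go with same-number libraries as duplicates. In the fit with a covariate, NRIP1 was lower at title numbers 25 to 32 than at 17 to 24 under each prefix. The differences were -1.02 ± 0.21 log2 under S6 and -1.73 ± 0.21 under S7, against 0.49 ± 0.21 for RIP140 against none. The standard errors of that fit can be too small. In the main fit NRIP1 differed by -0.86 ± 0.50 under S6 and -1.65 ± 0.51 under S7, neither past the test. Mean LCOR was lower with RA than with vehicle under every siRNA label. These divisions, like those of CYP26A1 and TFF1, ran over the same title numbers under S6 and S7. TFF1 split each labelled pair, and labelled pairs were as dispersed as random pairings, which argues against them as duplicates.

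The second library labelled E2+RA without siRNA had 5371 genes at 0, against 8906 to 10069 in the others of that siRNA label. Deeper sequencing is unlikely, because 5489 genes stayed at 0 after thinning to the smallest total, against 8667 to 10161 in other libraries. The label itself does not account for it, as the other libraries labelled E2+RA had at least 9028. Reads from DNA or unspliced RNA may account for it, since over genes silent elsewhere its counts rose with exonic length (rho = 0.512) and RNA of another cell type would concentrate in fewer genes than the 3.04% held by the 10 highest.

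Many genes differed under the RIP140 label. Lowering of NRIP1 is unlikely to be the cause, because NRIP1 was not lower in either fit, at 0.49 ± 0.21 log2 with a within-group component (edgeR adjusted p = 0.067). Gene length and GC content are unlikely as the whole cause, since with that trend removed 1684 genes passed, 1103 of them among the 2265. RIP140 minus none and both minus LCoR, which share no library, correlated at r = 0.781 over genes. Handling of the S6 and S7 series or the siRNA would each give this, so the correlation cannot tell them apart. NRIP1 argues against the siRNA as labelled, since it was lower within each prefix, at title numbers 25 to 32, and not between prefixes. With the within-group component these differences were -1.02 ± 0.21 log2 under S6 and -1.73 ± 0.21 under S7, though in the main fit neither passed the test.

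Random splits of the same libraries into groups of 8 were compared with the labelled split, in 100 splits each, in fits without the other libraries. For the LCoR label the labelled split called 3 genes, 4 splits, itself included, called at least as many and the highest other called 3780. For the same label on top of RIP140 siRNA these were, counted the same way, 7, 4 and 6062, for the RIP140 label 2424, 2 and 2757, and for both siRNAs 1198, 3 and 2511. The highest other splits followed odd or even title numbers in 14 of 16 libraries, so a split near that structure can give more genes than the siRNA labels. Over all other splits the median was 0 genes. Their count rose only weakly with the match to odd or even numbers, with Spearman rho from 0.162 for the LCoR label to 0.359 for both siRNAs.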

How the results depend on the processing

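The fits with a within-group component, with a length and GC offset and without the second E2+RA library were tests chosen after the data were seen, and the other settings were planned. Averaging over the 4 siRNA labels gave 2842 genes for E2 against vehicle, 3217 for E2+RA against vehicle and 2703 against RA, from 4 times the libraries, and turned NRIP1 for E2+RA against E2 to -0.009. With vehicle libraries only, LCoR gave 0 genes, RIP140 1, both siRNAs 0 and LCoR on top of RIP140 0, LRAT under both siRNAs turned to -0.029 and LCOR for LCoR on top of RIP140 to 0.131. Without a low-count filter LCoR on top of RIP140 gave 7 genes, and a stricter filter gave 8 for LCoR. Fitting only the groups compared gave 2 genes for E2, 15 for E2+RA against vehicle, 0 against RA, 0 for LCoR, 1492 for RIP140, 247 for both siRNAs and 3 for LCoR on top of RIP140. DESeq2 gave 526, 1174, 111 (against E2) and 934 for the ligand comparisons, 26 for LCoR, 51 for LCoR on top of RIP140 and 1 for the interaction of E2 with RIP140. With the within-group component these were 1550 for E2, 3367, 96 and 2735 for E2+RA against vehicle, E2 and RA, 64 for LCoR, 5852 for RIP140, 5288 for both and 145 for LCoR on top of RIP140. The length and GC offset gave 12 for LCoR. Of the list calls, 5 remained with an estimated correlation and fry made 8. Leaving out 1 library, with the lone sample left assumed to vary like other groups, gave 88 to 208 genes for E2, 153 to 441 for E2+RA against vehicle, 0 to 252 against E2, 92 to 394 against RA, 0 to 93 for E2 by RA, 3 to 8 for LCoR, 1279 to 3301 for RIP140, 787 to 2533 for both and 4 to 11 for LCoR on top of RIP140, with 0 to 0 for the RA label and the other interactions. LCOR ranged from -0.969 to 1.063 for E2, from -1.25 to 0.247 for RA, from -0.981 to 0.499, from -1.18 to 0.53 and from -0.09 to 0.616 for E2+RA against vehicle, E2 and RA, and from -0.073 to 0.342 for LCoR, and NRIP1 from -0.579 to 1.258 for RA. The cause of these moves was not tested. At these totals depth limits only the genes with few counts.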

Other observations

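The tests in this part were chosen after the values were seen. Some interferon response genes, picked here for their level, were high in every library. IFI27 stood at 12.36 to 13.40 log2 CPM, IFI6 at 10.89 to 12.12 and ISG15, a ubiquitin-like modifier, at 10.35 to 11.75, while KRT8, the luminal keratin, led all genes at 12.47 to 13.81.

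Averaged over the siRNA labels, the E2 label also went with changes in genes of lists that were not called. KRT17 fell by 1.68 ± 0.18 log2, CYR61 by 1.20 ± 0.15, SLC2A1, a glucose transporter, by 1.28 ± 0.29 and NR4A1, an immediate early nuclear receptor, by 1.79 ± 0.36 (edgeR, 16 groups of 2 libraries). AXIN2, a Wnt target, rose with EGFR and CYP1A1, by 1.73 ± 0.48, 1.32 ± 0.21 and 1.92 ± 0.33 log2. Of 26 retinoic acid targets 16 were higher and 0 lower.

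Labelled duplicates differed most in estrogen-responsive genes. The median standard deviation within labelled groups was 1.33 log2 for estrogen-induced genes against 0.29 for random lists. It was 0.90 against 0.37 for retinoic acid targets, so these also varied within labelled pairs. For S phase genes it was 0.63 against 0.28 and for luminal markers 0.60 against 0.28, with 0.27 for interferon response. PDZK1 ranged from -1.59 to 6.33 log2 CPM, CXCL12 from 0.01 to 6.97 and AREG from 0.42 to 6.79. The spread ran the same way by odd and even title number in TFF1 in every labelled pair. The 1.73 log2 median of estrogen-induced genes between even and odd numbers comes from the same differences within pairs. It gives their direction, and the spread is no separate evidence that labelled pairs hold 2 conditions. With a within-group component included the RIP140 label gave 5852 genes. That component was taken from the same spread, so this count says nothing on the cause of the spread.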
